A study of Anguilla anguilla with 6 samples.

How the data were processed

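Gonad pieces from the anterior, middle and posterior ovary of each eel had been pooled and kept in RNAlater, and total RNA was isolated with a miRNeasy kit, per the labels' protocols. Each animal gave 1 library made from 1 microgram of total RNA with an Illumina mRNA kit, per the labels' protocols. The phenotype label puts 4 libraries in the responder group and 2 in the non-responder group. No batch, date or pairing is given by the labels, which also do not define a response.

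The values come from 1 table of the authors' own comparison, whose name credits DESeq; the tool's version, the aligner, the counter and the genome build are not given in the sources used here. It holds 45974 gene models with best protein match, description, gene ontology terms and transcript lengths. The authors deposited a mean signal over all libraries and per condition, which per the file headers is a base mean, meaning counts divided by size factors and called scaled counts here. The deposited fold is the ratio of the condition means. The authors deposited a p-value per model and an adjusted p-value.

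What the conditions stand for was tested on the values. The mean over all libraries equals 0.33 of condition A plus 0.67 of condition B in each row, with a largest deviation of 3.5e-10, so A pools 2 libraries and B 4, and these are the non-responders and the responders by their numbers. The deposited adjusted p-value is close to the Benjamini-Hochberg adjustment of the p-value over 37072 models but not equal to it, with a largest deviation of 5.4e-05. The 8902 models without a p have a mean of 0. A further 6 columns with values per library carry names that match no library's label, and they were not used. Arithmetic on the condition means can show which of them enter which mean, but libraries were not assigned to groups by their values. As a result depth per library, spread between animals, leave-one-out fits and a count test were not analysed here, and the authors' p-values stand in place of a test of the counts, as the design written in advance provides for a table of means and folds. A further row, 1 in all, holds no values and was left out.

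A log2 of the deposited fold was computed, and a model was called at a deposited adjusted p under 0.05. Models listed at 0 in 1 group, 3616 in non-responders only and 1052 in responders only, have no finite log2. The named models were chosen by a rule fixed before the data were examined. It takes the 10 largest rises and the 10 largest falls among called models with a mean of at least 50 and a name, 1 model per name. It adds the called members of the receptor, steroidogenesis and yolk lists. From any other list with a called member it takes the members with the smallest p, called or not. Where a list has none called, it takes the 2 with the smallest p. All models of FSHR, LHCGR, CYP19A1 and VLDLR are added as well. Some models that the rule names are not reported here. The part of the rule that asks all responders to lie on one side of the non-responders needs values per library and was not applied.

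The 21 gene lists were also fixed before the data were examined, and models were matched to them by name or description. A match whose description named another protein was left out once the table's descriptions could be read, which removed 40 models, 0 of them called. All 32673 named models (71.1%) took their names from the deposited table, since 0 identifiers matched the reference gene table, and no coordinates were used. Lists were tested with the camera test on statistics computed beforehand (cameraPR of limma 3.58.1 in R 4.3.3) over 23266 models with a mean of at least 5. The statistic was a z-score from the deposited p with the sign of the fold. The preset correlation was 0.01, and p-values were adjusted by Benjamini-Hochberg over the lists. Such a p compares the models of a list with the other models and does not measure the spread between animals. An estimated correlation and the fry test need values per library and were not run. Counts adjusted over the list alone re-adjust the deposited p within 1 list.

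Ontology terms with 10 to 500 tested models were tested by a one-sided Fisher's exact test of called models against 18868 annotated models with a mean of at least 5, separately for rises and falls, with Benjamini-Hochberg adjustment. A rank test of all terms with cameraPR was added after the data were seen. For matched comparisons, 10000 random lists were drawn with the same numbers in 20 bins of mean, or in those bins crossed with 5 bins of transcript length, and their central 95% was taken. On independent simulated z-scores for the 23266 models, 100% of 200 models shifted by 6 were recovered and 5.21% of calls were false. A set of 40 models shifted by -1 had an adjusted p of 0.0158 in the limma test. Of 500 unshifted sets, 2.8% had a p under 0.05. Models that vary together, as those of 1 list can, were not simulated, so these rates do not calibrate the list tests. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

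The alternatives tried were other thresholds of the adjusted p, re-adjustment over models with higher means, other filters, preset correlations and ranks for the lists, pseudocounts of 0.5, 1 and 4 and equal group sums for the list medians, and other calls and backgrounds for the ontology terms. The deposited group means depend on the authors' size factors. Transcripts of near-identical copies or split models share or divide reads in a way that the table does not show, so a count of models is not a count of genes.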

Results

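Ovaries of 6 European eels (Anguilla anguilla) raised on a commercial farm were profiled by mRNA sequencing after 4 weekly treatments with gonadotropins, the pituitary hormones that drive ovarian growth. The labels class 4 animals as responders and 2 as non-responders, and each library carries its own animal tag. The comparison asks how the ovarian transcriptome of eels that respond to the hormone differs from that of eels that do not. Expression was taken from the authors' deposited table, which gives a mean scaled count per group, a fold and a p for 45974 gene models with identifiers from g1 upward. A p was given for 37072 models, and 23266 had a mean of at least 5 scaled counts over all 6 libraries. Values per library and read depth per library were not used here, so the values carry no SD. All log2 values are responder over non-responder.

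Transcripts of egg envelope proteins were abundant in both groups of ovaries. Of the 10 models with the highest mean over all 6 libraries in the authors' deposited table, 2 had no name or description and 5 were named or described as zona pellucida proteins of the egg envelope, led by ZP2 (g45297) at 254959 scaled counts in non-responders and 171541 in responders. Cyclin B1 (g2311), the regulatory partner of the kinase that drives entry into M phase, was also among these 10. They held 9.99% of the summed non-responder means and 8.18% of the summed responder means. The group sums in the authors' deposited table were 12635190 scaled counts in non-responders and 11695525 in responders.

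Responder ovaries differed from non-responder ovaries in 68 gene models, 45 higher and 23 lower at the authors' adjusted p under 0.05 in the authors' deposited table. Among the called models with a name and a mean of at least 50 scaled counts, the largest rises were those of GalNAc-transferases, which start mucin-type O-glycosylation, of the SOX family transcription factor SOX19A, and of noggin-2, a secreted antagonist of BMP signalling. The models that fell included 2 of PIWIL1, an Argonaute protein that binds piRNAs in germ cells, a retinol reductase, the splicing regulator TRA2B and a subunit of the proteasome activator. All 68 differed by more than 2-fold. An unadjusted p under 0.05 was given to 1360 models, 769 higher and 591 lower. They made up 3.67% of all models with a p. Without any difference a share of 5% would be expected only if p-values were spread evenly, which low counts can prevent. The share was 5.61% among models with a mean of at least 5 and 6.48% among those with a mean of at least 50. A name was given to 56 of the 68.

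Among the named rises, the GalNAc-transferase 8 model g36862 went from 4.30 scaled counts in non-responders to 139 in responders in the authors' deposited table (log2 5.02, adjusted p = 8.2e-08). The GalNAc-transferase-like 4 model (gltl4, g35535) went from 8.67 to 209 in the authors' deposited table (log2 4.59, adjusted p = 2.4e-06). SOX19A (sx19a, g1730) rose from 78.4 to 1073 in the authors' deposited table (log2 3.77, adjusted p = 5.1e-06), and noggin-2 (g22318) rose from 66.2 to 771 (log2 3.54, adjusted p = 1.1e-04). Syntenin-1 (sdcb1, g3059), a scaffold that binds syndecans, rose from 7.99 to 71.2 in the authors' deposited table (log2 3.16, adjusted p = 0.0046). The germ cell-specific gene 1-like protein (gsg1l, g7825) rose from 23.98 to 183 (log2 2.93, adjusted p = 5.6e-05) and the tyrosine kinase TEC (g9518) from 47.6 to 285 (log2 2.58, adjusted p = 0.0011) in the authors' deposited table. The other named rises in the authors' deposited table were threonine dehydratase (thd1, g20724, log2 2.70), mitochondrial enolase superfamily member 1 (enof1, g9613, log2 2.60) and the glycerol-3-phosphate transporter (glpt, g8940, log2 2.49).

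Of the falls, 9 models met the rule for naming. The all-trans-retinol reductase (retst, g15854) fell from 433 to 59.8 scaled counts in the authors' deposited table (log2 -2.86, adjusted p = 1.2e-11). TRA2B (g14165) fell from 199 to 33.7 (log2 -2.56, adjusted p = 3.5e-07) and the proteasome activator subunit 2 (psme2, g19578) from 310 to 75.4 (log2 -2.04, adjusted p = 5.6e-05) in the authors' deposited table. A PIWIL1 model (piwi, g18354) fell from 2149 to 766 in the authors' deposited table (log2 -1.49, adjusted p = 0.0020), whereas a longer model of that name (g8113), at 112 against 87.6, did not pass (log2 -0.36). The other falls in the authors' deposited table were beta-galactosidase-1-like protein 2 (glbl2, g14524, log2 -2.07), threonine synthase-like 1 (thns1, g13591, log2 -1.65), NAD kinase (nadk, g18057, log2 -1.48), tubulin alpha-1C (tba1c, g4799, log2 -1.47) and an axonemal dynein heavy chain (dyh10, g31552, log2 -1.35). These names come from the best protein match, and several models can share 1 name, as split pieces of a transcript or as duplicate genes. Re-adjusting the authors' p over models with a mean of at least 20 gave 63 higher and 27 lower models, with 61 of the 68 among them. The other 7 have means under 20 and were removed by that filter.

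**Figure D1:**
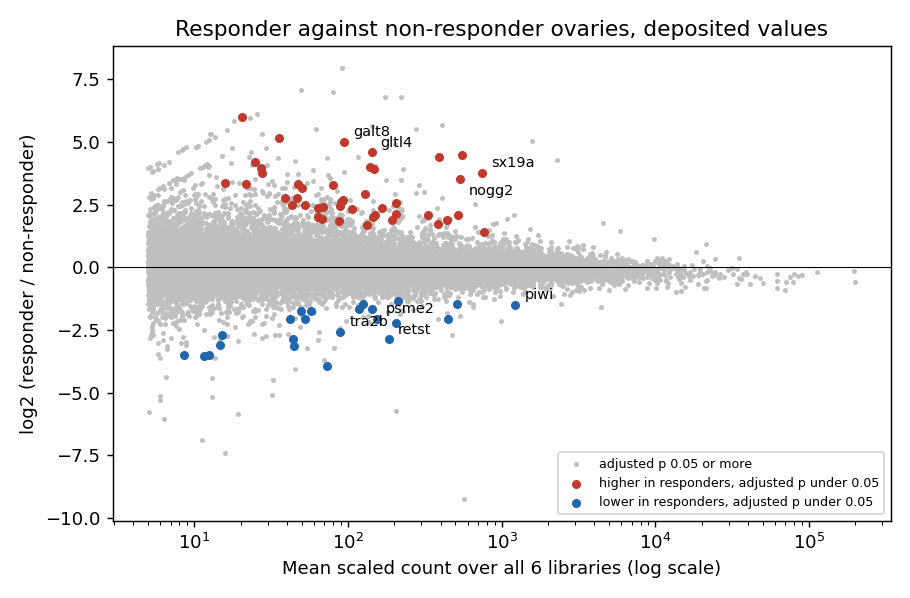
Each point is a gene model with a mean of at least 5 scaled counts, with the mean over all 6 libraries on a log axis against the log2 of responder over non-responder mean; red points are higher and blue points lower at adjusted p under 0.05 in the authors' deposited table, and labels give 8 of the named models. Models listed at 0 in 1 group have no finite log2 and are not drawn, among them the called model of neural-cadherin, at 0 in non-responders. The called models drawn lie at log2 1.43 or above and -1.35 or below.

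Oocyte transcripts were lower in responders as a group. Of 44 tested models of the oocyte and egg envelope list, matched to 20 listed genes, 40 lay below and 4 above a ratio of 1. Their median log2 was -0.37 (interquartile range -0.68 to -0.18, limma camera adjusted p = 1.8e-11). With a preset correlation of 0.05 between genes, the limma camera adjusted p was 3.0e-05. Both p-values count gene models, not genes or animals, and the contrast rests on 2 non-responders. Both models that fell over all genes tested were PIWIL1, g18354 and g33211, the latter at 84.8 against 20.3 scaled counts in the authors' deposited table (log2 -2.07, adjusted p = 0.0023). Adjusted over the list alone, 6 models fell, another PIWIL1 model (g10108), ZAR1 (g14809), ZP3 (g16004) and ZP4 (g11772) being the others. ZAR1, a maternal factor needed for the start of embryonic development, had 21663 scaled counts in non-responders and 11238 in responders in the authors' deposited table (log2 -0.95). The ZP3 model g16004 had 101754 and 54239 in the authors' deposited table (log2 -0.91). Rescaling both groups to equal sums would add 0.11 to every log2 and leave the median of this list at -0.26. None of the 5 marker lists of other cell types passed its test; the 4 adipocyte models had a median log2 of 0.93, and their list passed at adjusted p = 0.0481 without a filter on the mean.

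Transcripts of the list for storage of 5S ribosomal RNA in oocytes were lower as a group. The list of 8 models, which also holds RPL5 and RPL11, had a median log2 of -0.88 (bootstrap interval -1.0 to 0.01), with 6 models below and 2 above a ratio of 1 (limma camera adjusted p = 3.4e-04). None passed over all genes tested in the authors' deposited table, and 2 fell when adjusted over the list alone. The lower of these p-values belonged to 42Sp43 (p43, g17095), at 381 scaled counts against 203 in the authors' deposited table (log2 -0.91). The other was transcription factor IIIA (tf3a, g2401), which binds 5S RNA and its gene, at 3802 against 2101 in the authors' deposited table (log2 -0.86). The 8 models were matched to only 4 listed genes. Of them, 5 were models of transcription factor IIIA and 42Sp43, all lower in the authors' deposited table (log2 -1.07 to -0.86). The camera p counts each such model, although they can be copies or pieces of 1 gene.

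Ribosomal protein and mitotic cell cycle transcripts were also lower as groups. Of 117 ribosomal protein models, 86 lay below and 31 above a ratio of 1, with a median log2 of -0.19 (interquartile range -0.37 to 0.00, limma camera adjusted p = 2.4e-05), and none passed over all genes tested or adjusted over the list alone. The 2 ribosomal protein models with the smallest p in the authors' deposited table were RPS27L (g1839, 239 against 555 scaled counts, log2 1.22) and RPL37A (g8371, 2760 against 1538, log2 -0.84). Of 61 mitotic models, matched to 21 listed genes, 47 lay below and 14 above a ratio of 1. Their median log2 was -0.24 (interquartile range -0.42 to -0.04, limma camera adjusted p = 5.1e-04), and none passed either adjustment. The smallest p-values of that list in the authors' deposited table belonged to a ribonucleotide reductase subunit model (rir1, g37684, 83.7 against 41.2, log2 -1.02) and to topoisomerase 2-alpha (g24950, 100.5 against 58.0, log2 -0.79). With a preset correlation of 0.05 between genes, the adjusted p of the ribosomal list was 0.0533 and that of the mitotic list 0.0719. With both groups rescaled to equal sums, the median log2 was -0.075 for the ribosomal list and -0.13 for the mitotic list. That rescaling raises every model by the same amount, so both lists stay as far below the other models as before.

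Steroidogenic transcripts were higher in responders as a group. Of 35 models, matched to 18 listed genes, 27 lay above and 8 below a ratio of 1. Their median log2 was 0.36 (interquartile range 0.05 to 0.57, limma camera adjusted p = 0.0072), against a camera adjusted p of 0.114 with a preset correlation of 0.05. No model passed over all genes tested, and 1 rose when adjusted over the list alone, 17-beta-hydroxysteroid dehydrogenase type 1 (HSD17B1, g21029), which reduces estrone to estradiol. It had 86.8 scaled counts in non-responders and 257 in responders in the authors' deposited table (log2 1.57, adjusted p = 0.057). The nuclear receptor NR5A2 (g8768) had 41.97 and 80.1 scaled counts in the authors' deposited table (log2 0.93) and did not pass. Both models of CYP19A1, the aromatase that makes estrogens, had low values in the authors' deposited table, 23.0 against 11.9 for g9348 (log2 -0.95) and 24.3 against 21.2 for g9349 (log2 -0.20), and neither passed.

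Transcripts of the hormone receptors showed no group difference past the threshold. The receptor list of 25 models had a median log2 of -0.03, with 12 models above and 13 below a ratio of 1 (limma camera adjusted p = 0.40), and no model passed over all genes tested or over the list alone. The FSH receptor (g10501) had 3.45 scaled counts in non-responders and 5.85 in responders in the authors' deposited table. Both models of the LH receptor were listed at 0 in non-responders in the authors' deposited table, with 0.27 (g12514) and 0.49 (g40338) scaled counts in responders. The smallest p-values of the list belonged to insulin receptor models, at 147 against 73.4 for g18242 (log2 -1.003) and 20.3 against 8.68 for g40102 (log2 -1.22) in the authors' deposited table.

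Yolk and lipid uptake transcripts showed no group difference either, with 42 models at a median log2 of -0.01, 20 above and 22 below a ratio of 1 (limma camera adjusted p = 0.69). VLDLR, the receptor through which fish oocytes take up vitellogenin, had 4 models in the authors' deposited table, at 5811 against 5190 (g14275), 8180 against 6335 (g14276), 1279 against 1840 (g1875) and 426 against 283 (g40667) scaled counts, and none passed. Cubilin (g39579, 65.0 against 32.6, log2 -0.99) and the lipid droplet protein perilipin-2 (g14812, 507 against 881, log2 0.80) had the smallest p-values of that list in the authors' deposited table. Lipid synthesis and storage had 24 models at a median log2 of 0.39 (adjusted p = 0.16), with ELOVL5 (g6746) at log2 1.06 and ELOVL6 (g18541) at log2 -0.91 in the authors' deposited table. Cholesterol synthesis had 17 models at a median log2 of 0.01 while its test leaned lower (adjusted p = 0.96), with SC5D (g23363) at log2 -0.61 and DHCR7 (g1462) at log2 0.55 in the authors' deposited table. None of the models in these 3 lists passed over all genes tested or adjusted over the list alone.

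Growth factor, meiotic and matrix lists did not pass. The TGF-beta and growth factor list had 33 models at a median log2 of 0.05 (adjusted p = 0.81), and its smallest p-values belonged to a pair of BMP2 models at log2 3.93 (g1844, 21.6 against 328) and 1.83 (g816) in the authors' deposited table, with an adjusted p = 0.59 for the former. Of 5 meiotic prophase models (median log2 -0.05, adjusted p = 0.33), the meiotic cohesin SMC1B (g5613) fell when adjusted over the list alone, at 494 scaled counts against 229 in the authors' deposited table (log2 -1.11). Extracellular matrix had 40 models at a median log2 of 0.19 (adjusted p = 0.33), with TIMP2 (g24267) at log2 0.95 and COL6A3 (g6412) at log2 -0.64 in the authors' deposited table.

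Markers of other cell types that an ovary piece can hold gave no list past the threshold. Median log2 values were -0.04 over 8 erythrocyte models (adjusted p = 0.81), -0.29 over 11 endothelial models (adjusted p = 0.18), 0.28 over 10 leukocyte models (adjusted p = 0.40), 0.09 over 13 smooth muscle models (adjusted p = 0.97) and 0.93 over 4 adipocyte models (adjusted p = 0.15, and 0.0481 without a filter on the mean). VE-cadherin (CDH5, g17569), a junction protein of endothelial cells, fell when adjusted over its list alone, with 95.4 against 37.4 scaled counts in the authors' deposited table (log2 -1.35), and another CDH5 model (g38811) had a log2 of -1.63. The smallest p-values of the remaining marker lists in the authors' deposited table belonged to SLC4A1 (g2522, log2 -0.81) and CAHZ (g17409, log2 1.76) for erythrocytes and to SPI1 (g13044, log2 0.71) and CORO1A (g4014, log2 1.26) for leukocytes. Those of smooth muscle were CNN1 (g14833, log2 -1.15) and MYL9 (g17901, log2 0.61), and those of adipocytes PLIN1 (g8968, log2 0.94) and CEBPA (g16641, log2 0.92), in the authors' deposited table.

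Stress and housekeeping lists did not pass. Median log2 values were 0.03 over 33 apoptosis and lysosome models (adjusted p = 0.41), -0.02 over 23 stress response models, whose test leaned higher (adjusted p = 0.94), 0.03 over 54 oxidative phosphorylation models (adjusted p = 0.59) and 0.10 over 72 proteasome models (adjusted p = 0.40). None of their models passed over all genes tested or adjusted over the list alone. BAX (g3504), an effector of mitochondrial apoptosis, had 550 against 1068 scaled counts (log2 0.96) and BCL2 (g7294) a log2 of 1.13 in the authors' deposited table. FOS (g12409) was at log2 0.72 and EGR1 (g24714) at log2 -1.16 in the authors' deposited table. An ATP synthase subunit (at5f1, g44169, log2 0.95), its subunit O (atpo, g8091, log2 0.81) and a pair of PSMD8 models (g23352, log2 0.90, and g43328, log2 2.18) had the smallest p-values of the last lists in the authors' deposited table.

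**Figure D2:**
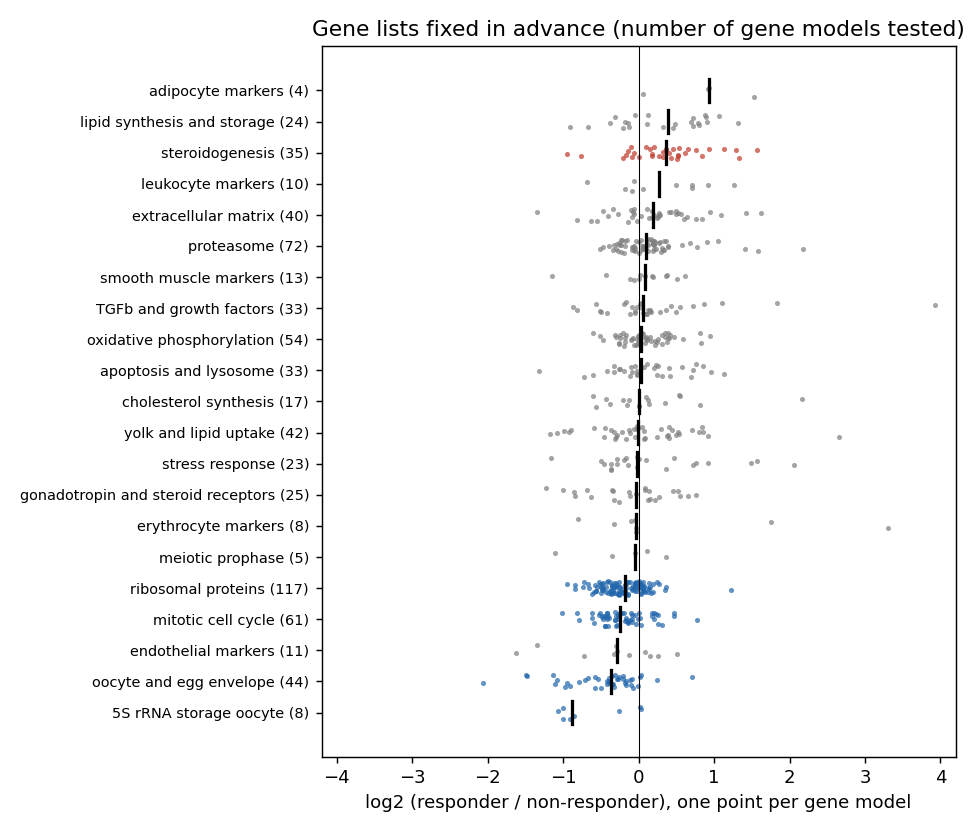
Log2 of responder over non-responder mean for each tested gene model of the 21 lists, from the authors' deposited table, with the number of models in brackets, a black bar at each median and points spread vertically only for visibility; red lists were higher and blue lists lower by limma camera at adjusted p under 0.05, and grey lists did not pass. The blue lists have medians of -0.88, -0.37, -0.24 and -0.19, and the red list has 0.36.

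Gene ontology terms were tested to see which functions the called models hold beyond these lists. Among 40 annotated rises, 4 of 3279 terms were enriched by Fisher's exact test, led by polypeptide N-acetylgalactosaminyltransferase activity with 4 called models of 31 (adjusted p = 0.0017). The other enriched terms were calcium-dependent cysteine-type endopeptidase activity and protein autoprocessing, with 3 of 15 each (adjusted p = 0.0043), and blastocyst development with 3 of 28 (adjusted p = 0.023), all 3 resting on calpain-2 models. Fisher's exact test counts each model on its own, and whether short models that share a name, such as those of GalNAc-transferase 8 with 168, 411 and 730 bases, are pieces of 1 gene was not resolved. All 4 terms can therefore rest on fewer genes than models. Among 15 annotated falls, 0 terms passed by Fisher's exact test, and 69 of the 3279 had an unadjusted p under 0.05.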

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

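The preset correlations, the ranks, the thresholds of 0.01 and 2-fold, the minimum mean of 50, the wider ontology background and the equal-sum scaling were chosen after seeing the data. The number of called models stayed within 1.5 times of 68 under each alternative, from 46 at adjusted p under 0.01 to 96 under 0.1. Re-adjusting over models with a mean of at least 5 kept all 68 and added 14. At a mean of at least 50 it kept 47 and added 18. The 21 lost there have means under 50, so the filter removed them and none failed the re-adjustment. Of the comparisons of gene lists, 98 kept direction and side of the threshold. The oocyte and 5S storage lists passed under every alternative run. With a preset correlation of 0.05, adjusted p was 0.114 for steroidogenesis, 0.0719 for the mitotic list and 0.0533 for ribosomal proteins, in the same direction, since a higher correlation widens the test's error; under the other alternatives it ran from 0.0012 to 0.0082, from 5.9e-06 to 0.0016 and from 4.1e-11 to 9.2e-05. Without a filter on the mean the adipocyte list passed at 0.0481, against 0.0845 to 0.232 under the others, and the TGF-beta and cholesterol lists turned direction at 0.974 each, as did cholesterol with ranks at 0.985; none of these reversed lists passed in any setting, and the cause was not tested. HSD17B1 (g21029) passed at 0.0357 and 0.0286 when fewer models, with means of at least 5 and 20, were adjusted over. The 6 comparisons of ontology terms gave 3 or 4 higher and 0 lower terms. Pseudocounts of 0.5, 1 and 4 on the deposited group means kept the direction of all 68 called models and moved no list median outside its bootstrap interval. Equal group sums add 0.11 to every log2, by construction, so no list changes its distance from the other models. The medians move to -0.26 for the oocyte list, -0.13 for the mitotic list, -0.075 for ribosomal proteins and 0.16 for TGF-beta. Those of oxidative phosphorylation and the proteasome move to 0.14 and 0.22. The medians of the receptor, yolk, meiotic, erythrocyte and stress lists, none past the threshold, then lie above 0. Other normalizations per library, count tests and leaving out a library were not run. They need the 6 columns of values per library, whose names match no animal; arithmetic on the condition means can show which columns enter which mean, but groups were not inferred from values. No paired analysis was possible because the replicate numbers only name the animals and the deposited means carry none. Depth per library was not analysed here, so how far it limits weakly expressed models stays open.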

Other observations

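The tests of length, abundance, cell-type markers and 5S storage models in this part, the ontology rank test and the models named here outside the rule were chosen after the results were seen; the test of the piRNA term without the oocyte list was fixed before its result. Several rises came in groups that share a protein name. All 3 tested models of GalNAc-transferase 8 were called, the others being g40645 (36.1 against 814 scaled counts, log2 4.50) and g36679 (26.7 against 571, log2 4.42) in the authors' deposited table. For calpain-2, a calcium-dependent protease, 7 of 8 models were higher and 3 called, for the tyrosine kinase TEC 2 of 2 were called, and for gsg1l 2 of 3. Another SOX family model rose beside SOX19A, the pluripotency factor SOX2 (g18599), from 2.19 to 22.7 in the authors' deposited table (log2 3.38, adjusted p = 0.034). Neural-cadherin (g2485) was listed at 0 in non-responders and at 18.6 in responders in the authors' deposited table (adjusted p = 0.0020). Mesothelin-like protein (g896), alpha-catulin (g390) and the orphan receptor GPR148 (g13103) fell, with log2 values of -3.12, -2.87 and -3.49 in the authors' deposited table.

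The ontology terms were also ranked over all models. The limma rank test put 19 terms higher and 62 lower in responders, and 0 and 4 with a preset correlation of 0.05. The smallest p belonged to the pi-body, the germ granule that holds piRNA proteins, with 16 models, 15 of them below a ratio of 1 (median log2 -0.45, adjusted p = 1.5e-05). Negative regulation of adenylate cyclase activity and piRNA metabolic process (adjusted p = 7.6e-05 each) and acrosin binding (adjusted p = 8.2e-05) came next, all lower in responders. Of the pi-body models, 8 belong to the oocyte list, with a median log2 of -0.90. The other 8 had a median of -0.21, inside the range of -0.31 to 0.35 for matched lists, but 7 of them lay below a ratio of 1, among them the tudor proteins RNF17 (g12118, log2 -1.18) and TDRKH (g5776, log2 -0.81) in the authors' deposited table. Whether the term's change rests on the oocyte list alone stays open.

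Some large ratios did not pass. Of 22 models with a mean of at least 50 and a log2 of size 4 or more, 17 had an adjusted p of 0.05 or more, 14 of them higher and 3 lower in responders, 1 of the lower ones (SCUBE2, g8995) being listed at 0 there. Chordin-like protein 1 (g1224), a BMP antagonist, had 2.35 scaled counts against 259 in the authors' deposited table (log2 6.78, p = 0.010). Aldehyde oxidase (g7514) had 1700 against 2.81 in the authors' deposited table (log2 -9.24, p = 0.0066), and caspase-1 (g18684) had 170 against 3363 (log2 4.30, p = 0.49).

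The oocyte list was lower in responders, at a median log2 of -0.37. Lists matched on abundance and transcript length had a median of -0.04 and a lower bound of -0.15, so a trend with these alone gave a smaller fall. Their models were drawn independently, so the bound is too narrow for models that vary together. Lipid synthesis (0.39, upper bound 0.30) and the proteasome (0.10, upper bound 0.055) also lay outside their bounds, without passing the limma camera test. A larger share of RNA from all 5 other cell types together in responders would raise the markers of each. A larger share of 1 type would raise only its own. Over 46 marker models the pooled median log2 was 0.04 (bootstrap interval -0.07 to 0.19). The adipocyte list was highest at 0.93 and the endothelial list lowest at -0.29. The adipocyte median, over 4 models, lay above its upper bounds of 0.80 for lists matched on abundance and length and 0.67 for abundance alone. The endothelial median lay under its lower bound of -0.25 for lists matched on abundance and length. It lay inside that of -0.37 for lists matched on abundance alone. A permutation test of the difference between the lists gave p = 0.0554. This test cannot exclude a larger share of 1 type, since such a share would also make the lists differ. A larger share of other cells therefore stays open, and follicle cells, for which no list was tested, could also take a larger share. A change within oocytes that goes with the response, such as growth past the stage that stores these transcripts, is a hypothesis that the design leaves open.

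The 5 models of transcription factor IIIA and 42Sp43 had a median log2 of -0.999, below the -0.37 of the 44 oocyte models by a difference of -0.63 (one-sided exact permutation test over gene models, p = 0.0203). They were picked after the 5S storage list had been seen to be lower, so this p restates that result and bears on no explanation of it.

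The steroidogenesis list was higher at a median log2 of 0.36. Lists matched on abundance and length had a median of -0.01 and an upper bound of 0.18, so that trend alone gave no such rise. This bound and that of the ribosomal list are also too narrow for models that vary together. The ribosomal protein list was lower at -0.19, under its lower bound of -0.11. Median log2 over all models went from -0.08 in the shortest to 0.08 in the longest of 5 bins of transcript length. The authors' size factors could add a constant to every model. It would move a list and its matched lists alike, so it can shift the medians but not put them outside these bounds. A larger share of steroid-producing follicle cells stays open for the steroidogenesis list, as no follicle cell list was tested.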
